A study of Homo sapiens with 12 samples.

How the data were processed

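Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out in HepG2 and Huh7, a pair of human liver-cancer cell lines, and in stably transfected cells of each line that carried HOXA13 with an HA epitope tag. HOXA13 is a homeodomain transcription factor encoded in the HOXA cluster. The 12 libraries were an antibody ChIP, a mouse IgG ChIP and an input from each of the 4 cell populations, with 1 library per condition. The antibody was raised against HOXA13 in the untagged cells and against the HA tag in the tagged cells. The 4 IgG libraries were not analysed here.

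Each of the 4 deposited peak lists was called on 1 ChIP library against the input of the same cells, per the file names. Reads were aligned with BWA and peaks were called with MACS2, per the submitters' processing notes; versions and settings are not given in the sources used here. The submitters' processing notes also name GRCh38, whereas the sequence names in the lists (a decoy sequence and GL000 contigs) are those of the GRCh37 reference with decoy, and 15 of 24 chromosomes carried peaks beyond the end of the GRCh38 chromosome. Coordinates are therefore printed as GRCh37, 1-based, and none was converted. The deposited fold was, per MACS2's published formulas, the ratio of the ChIP pileup to the pileup expected from input at the summit, with 1 added to each. The larger library was scaled down first, which was the ChIP in Huh7 anti-HOXA13, by a factor of 0.812, and the input in the other lists. The deposited significance values were −log10 p and −log10 q at the summit. The lowest −log10 p in the lists lay at 2.00 and the lowest −log10 q at 0, so the authors' deposited lists were limited at p of 0.01 and not on q. The deposited score was 10 times the −log10 p, truncated to a whole number, in at least 99.97% of peaks. The last deposited column was another whole number, the distance of the summit from the peak start.

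All values per peak are the authors' and were used to describe, rank and filter peaks within a list. From fold and p together, the whole-number ChIP pileup and the expected pileup at each summit were solved with MACS2's published formulas, which gave a solution for 99.99% or more of the peaks in each list. The expected pileup had a fixed lower level in each list, taken as the genome background, of 1.73 in HepG2 anti-HOXA13, 2.62 in HepG2 anti-HA, 2.60 in Huh7 anti-HOXA13 and 2.61 in Huh7 anti-HA. Taking the shortest peak as the fragment length and 2700000000 bp as the effective genome, these levels correspond to 45.2, 52.4, 70.3 and 61.8 M ChIP reads and to 86.2, 97.2, 57.1 and 79.6 M input reads (M, 1e6 reads), in the same order. The labels state 50 M reads per sample. A peak whose expected pileup was over 3 times the background was called a peak with raised input; such peaks mark sequence that collects extra reads in input as well. Strong peaks are those with −log10 q of 5 or more.

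Overlap was counted on chromosomes 1 to 22, X and Y with a minimum of 1 bp. Chance was estimated from 100 random placements of the counted list on the same chromosome, outside stretches of 1 Mb or more with no peak in any list, which stood in for assembly gaps. Another estimate of chance, also fixed before, shifted each peak by 10 to 50 kb. Shares carry exact (Clopper-Pearson) 95% binomial intervals and folds carry 95% Poisson intervals of the ChIP pileup. These intervals cover counting error only. No condition had a replicate among these samples, so no test between conditions was made; no control library was shared between lists. An exact two-sided binomial test on peaks that overlapped only 1 of a pair of other lists, adjusted by the Benjamini-Hochberg method over 8 tests, compares the libraries and not the conditions.

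The choices made before the data were examined were the 4 overlaps, regions in all lists, the chance models, stricter thresholds and equal list lengths (each list held to its 10414 best peaks by q). Chosen after the data were seen were the filter on raised input, q of 0.05, classes of fold, summit distances, the test of antibody against cell line, and counts by chromosome. Promoter shares, HOX13 sites at summits, gene lists and genes named by promoter peaks had also been planned and were not run, because no GRCh37 sequence or annotation was used here. In their place the 10 peaks with the highest fold per list on chromosomes 1 to 22 and X were taken as named regions, the same rule without the promoter condition, set after the files were seen. Regions shared by exactly a pair of lists were ranked by mean rank of fold.

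Scripts were written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated lists of 10000 summits, pileups were recovered for 100% of summits, 300 of 300 planted overlaps were found, and the chance model gave 19.4 overlaps where 20 were built in.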

Results

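ChIP-seq peaks were compared between HepG2 and Huh7 cells and between an antibody to HOXA13, used in untagged cells, and an antibody to the HA tag, used in cells carrying HA-tagged HOXA13. The comparisons ask which regions carry HOXA13 in liver-cancer cells, whether the tagged protein marks the regions found by the HOXA13 antibody, and which regions are common to the cell lines. Each of the 4 lists came from 1 library, so differences between lists have no replicate check.

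The anti-HA library of HepG2 had the most strong peaks of the 4 libraries. HepG2 anti-HA held 7537 strong peaks among 34849 on chromosomes 1 to 22, X and Y, whereas HepG2 anti-HOXA13 held 542 of 71999, Huh7 anti-HOXA13 held 266 of 10414 and Huh7 anti-HA held 115 of 28809. Peaks of at least 5-fold over input numbered 3813 in HepG2 anti-HA, 206 in Huh7 anti-HOXA13, 89 in HepG2 anti-HOXA13 and 22 in Huh7 anti-HA. Most of the other peaks were weak: 10.3% of HepG2 anti-HOXA13 peaks, 9.31% of Huh7 anti-HOXA13 peaks and 6.68% of Huh7 anti-HA peaks reached q of 0.05, against 51.2% in HepG2 anti-HA. The median summit stood on 7 ChIP fragments in HepG2 anti-HOXA13 and on 13, 14 and 11 in HepG2 anti-HA, Huh7 anti-HOXA13 and Huh7 anti-HA. Raised input underlay 82.5% (79.0 to 85.6%) of the strong HepG2 anti-HOXA13 peaks, 54.8% (45.2 to 64.1%) of the strong Huh7 anti-HA peaks, 31.8% (30.7 to 32.9%) of those in HepG2 anti-HA and 13.5% (9.66 to 18.2%) of those in Huh7 anti-HOXA13.

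In HepG2 anti-HA the highest fold lay at chromosome 4, 56435018 to 56435652, with 41.4-fold (35.1 to 48.6) from a pileup of 149 where 2.62 was expected. Chromosome 21, 9825450 to 9833610, followed with 38-fold (33.4 to 43.1). Next came chromosome 8, 99610079 to 99610803, with 33.9-fold (29.1 to 39.2) and chromosome 1, 29074636 to 29075145, with 32.8-fold (28.3 to 37.8). Of the 10 highest HepG2 anti-HA regions, 6 overlapped a Huh7 anti-HA peak, 2 a HepG2 anti-HOXA13 peak and 0 a Huh7 anti-HOXA13 peak. In Huh7 anti-HA only the chromosome 21 region exceeded 7-fold, at 12.9-fold (9.70 to 16.9). Chromosome 11, 37328269 to 37328574, with 6.36-fold (4.49 to 8.78) and chromosome 7, 92838996 to 92839257, with 6.09-fold (3.88 to 9.16) were next, and the chromosome 7 region stood at 16-fold in HepG2 anti-HA.

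The highest anti-HOXA13 regions differed between the lines. Huh7 anti-HOXA13 was led by chromosome 19, 2933346 to 2933871, at 13.7-fold (10.9 to 16.9), chromosome 17, 15619792 to 15620718, at 12.2-fold (9.37 to 15.7), and chromosome 16, 3458609 to 3459025, at 11.8-fold (8.84 to 15.4). None of its 10 highest regions overlapped an anti-HA peak of either line, and 3 overlapped a HepG2 anti-HOXA13 peak. Among its 206 peaks of at least 5-fold, 9 overlapped a HepG2 anti-HA peak, where shifts gave a mean of 1.83 and a maximum of 6. A Huh7 anti-HA peak was overlapped by 3 of them, where shifts gave a mean of 2.08. HepG2 anti-HOXA13 was led by chromosome 12, 20704355 to 20704503, at 22.9-fold (17.9 to 28.9), chromosome 1, 91852784 to 91853110, at 21.7-fold (18.3 to 25.5), and chromosome 8, 70602343 to 70602530, at 20.6-fold (16.9 to 24.9). HepG2 anti-HA enriched these regions too, by 6.55-fold, 10.1-fold and 19.95-fold, and 9 of the 10 highest HepG2 anti-HOXA13 regions overlapped a HepG2 anti-HA peak. Chromosome 21, 9825441 to 9826456, was enriched above 10-fold in 3 lists, at 17-fold in HepG2 anti-HOXA13, 38-fold in HepG2 anti-HA and 12.9-fold in Huh7 anti-HA. Chromosome 5, 71146750 to 71146877, also had peaks in 3 lists, at 13.6-fold in HepG2 anti-HOXA13, 5.30-fold in HepG2 anti-HA and 5.14-fold in Huh7 anti-HOXA13. Raised input lay under the HepG2 anti-HOXA13 peaks on chromosomes 1 and 21, and repeat annotation was not used here for these HepG2 regions on chromosomes 1, 5, 8, 12 and 21.

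Within HepG2, few anti-HA peaks were shared with the HOXA13 antibody, while the highest anti-HOXA13 peaks were often shared. Of 34849 anti-HA peaks, 1726 (4.95%, 4.73 to 5.19%) overlapped an anti-HOXA13 peak, 3.72 times the mean of 464 over random placements, whose range was 413 to 517. By strength of the anti-HA peak, 6.59% (6.24 to 6.94%) of peaks below 3-fold overlapped, against 2.78% after 10 to 50 kb shifts, and 1.41% (0.975 to 1.98%) of those from 5- to 8-fold, against 0.702% after shifts. At 15-fold or more, 9 of 262 (3.44%, 1.58 to 6.42%) did, against 1.34% after shifts. From the anti-HOXA13 side, 39 of the 89 peaks of at least 5-fold (43.8%, 33.3 to 54.7%) overlapped an anti-HA peak, against 8.75% after shifts, and without raised input 20 of 73 (27.4%, 17.6 to 39.1%) did, against 6.38%. Summits of overlapping pairs lay a median of 50 bp apart, against 105 bp after shifts. Against shifts in place of placements the excess over chance was 2.20 times. Of the 7537 strong anti-HA peaks, 294 overlapped 1 of the 542 strong anti-HOXA13 peaks, where shifts gave a mean of 98.6; without raised input 3 of 5141 overlapped 1 of 95, where shifts gave 0.31.

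Within Huh7 a smaller share of anti-HA peaks was shared, without a smaller excess over chance in the full lists. At equal list length 73 anti-HA peaks overlapped in Huh7 and 488 in HepG2, which was 3.28 and 3.47 times the shift means. Of 28809 anti-HA peaks, 184 (0.639%, 0.550 to 0.738%) overlapped an anti-HOXA13 peak, 4.45 times the placement mean of 41.4 (range 27 to 54) and 2.99 times the shift mean. None of the 115 strong anti-HA peaks overlapped a strong anti-HOXA13 peak, which allows a share of up to 3.16%. Among anti-HOXA13 peaks of at least 5-fold, 3 of 206 (1.46%, 0.301 to 4.20%) overlapped an anti-HA peak, where shifts gave a mean of 2.08. The regions found by both antibodies in Huh7 and by neither in HepG2 were led by chromosome 17, 12196666 to 12196826, at 4.79-fold with anti-HOXA13 and 4.99-fold with anti-HA, and chromosome 4, 126736745 to 126736885, at 4.34-fold and 3.60-fold.

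The anti-HA antibody found common regions in the tagged cells of both lines. Of 28809 Huh7 anti-HA peaks, 2550 (8.85%, 8.53 to 9.19%) overlapped a HepG2 anti-HA peak, 16.9 times the placement mean of 151 (range 125 to 183). Chromosome 7, 88020525 to 88021019, stood at 30.4-fold in HepG2 and 5.11-fold in Huh7, chromosome X, 148760662 to 148761174, at 25.4-fold and 5.33-fold, and chromosome 5, 82561012 to 82561492, at 19.4-fold and 5.62-fold, all absent from both anti-HOXA13 lists. Of the strong Huh7 anti-HA peaks, 81 of 115 (70.4%, 61.2 to 78.6%) overlapped a strong HepG2 anti-HA peak, where shifts gave a mean of 4.47. The stronger the HepG2 anti-HA peak, the more often Huh7 anti-HA held it: without raised input, 2.31% (2.08 to 2.56%) of peaks below 3-fold, 6.63% (5.56 to 7.83%) from 5- to 8-fold and 28.3% (22.8 to 34.4%) at 15-fold or more overlapped, the last against 0.947% after shifts. Summits of 2458 overlapping pairs lay a median of 63 bp apart, against 110 bp after shifts. Leaving out raised input lowered the overlap to 1094 peaks, 9.90 times the placement mean, and the strong overlap to 17 of 52 (32.7%, 20.3 to 47.1%).

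The HOXA13 antibody also found common regions in the lines, concentrated among its stronger Huh7 peaks. Of 10414 Huh7 anti-HOXA13 peaks, 257 (2.47%, 2.18 to 2.78%) overlapped a HepG2 anti-HOXA13 peak, 2.77 times the placement mean of 92.8 (range 76 to 124). For Huh7 peaks of at least 5-fold the share was 34 of 206 (16.5%, 11.7 to 22.3%), where shifts gave a mean of 3.11 and a maximum of 10. Chromosome 12, 133779114 to 133781185, stood at 5.29-fold in HepG2 and 7.94-fold in Huh7, chromosome 19, 37037921 to 37038614, at 4.52-fold and 7.22-fold, and chromosome 11, 119955368 to 119956423, at 5.14-fold and 5.93-fold. These regions held no anti-HA peak. Only 2 peaks (0.752%, 0.0912 to 2.69%) were shared when both lists were limited to strong peaks.

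Set side by side at equal list length, peaks of at least 5-fold in 3 lists met the other cell line's list of the same antibody more often than the same line's list of the other antibody. Of the 3813 HepG2 anti-HA peaks of at least 5-fold, 268 overlapped Huh7 anti-HA and 18 overlapped HepG2 anti-HOXA13 (exact binomial test, adjusted p = 2.32e-59). Of the 206 Huh7 anti-HOXA13 peaks, 14 overlapped HepG2 anti-HOXA13 and 0 overlapped Huh7 anti-HA (exact test, adjusted p = 0.000326). Of the 22 Huh7 anti-HA peaks, 10 overlapped HepG2 anti-HA and 0 overlapped Huh7 anti-HOXA13 (exact test, adjusted p = 0.00312). HepG2 anti-HOXA13 went the other way, with 5 of 89 in Huh7 anti-HOXA13 and 16 in HepG2 anti-HA (exact test, adjusted p = 0.0220), and without raised input its counts of 4 and 7 of 73 did not differ detectably (adjusted p = 0.508, exact test). The test takes no account of chance overlap, which differed between the lists compared. For HepG2 anti-HOXA13, shifts gave means of 0.22 in Huh7 anti-HOXA13 and 1.84 in HepG2 anti-HA. Its higher count in HepG2 anti-HA thus does not mean a larger excess over chance. Shift means were 11.66 and 4.93 for HepG2 anti-HA, 0.63 and 0.72 for Huh7 anti-HOXA13, and 0.07 and 0.04 for Huh7 anti-HA. Equal length does not make the lists equally strong. Strong peaks numbered 7537 in HepG2 anti-HA, 542 in HepG2 anti-HOXA13, 266 in Huh7 anti-HOXA13 and 115 in Huh7 anti-HA. For peaks of every list but HepG2 anti-HA, the larger count was in the list with more strong peaks. Antibody or cell line cannot be told apart from list strength there. For HepG2 anti-HA the larger count was in Huh7 anti-HA, which had fewer strong peaks. Peaks are not replicates, and the p-values describe the libraries.

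Only 4 regions held a peak of every list, against a mean of 0.46 (range 0 to 2) after shifts. They lay at chromosome X, 61686509 to 61686813 and 58581766 to 58581956, chromosome 17, 22245537 to 22245993, and chromosome 3, 156892591 to 156893002. Folds at these regions ran no higher than 2.65, which was reached on chromosome 17 in HepG2 anti-HOXA13. Raised input was present at all 4 regions in every list, and no region in every list remained without such peaks or among strong peaks.

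Weak peaks had a similar profile over the chromosomes with both antibodies of HepG2 and another profile in Huh7. Among peaks with q above 0.05, chromosome 20 held 5.30 times (5.17 to 5.44) the density of the median autosome in HepG2 anti-HOXA13 and 5.98 times (5.68 to 6.30) in HepG2 anti-HA. Chromosome 16 held 3.09 and 3.18 times, chromosome 2 held 2.29 and 3.52 times, chromosome 6 held 1.69 and 2.66 times and chromosome 14 held 1.69 and 2.04 times, in the same order. In Huh7 chromosome 20 stood at 1.33 times (1.17 to 1.498) with anti-HOXA13 and 1.23 times (1.14 to 1.32) with anti-HA. Huh7 showed contrasts between arms instead: 9q held 4.94 peaks per Mb and 9p 1.12 with anti-HOXA13, and 11.9 and 2.94 with anti-HA, while 20p held 7.12 and 20q 2.39 with anti-HOXA13, and 18.3 and 7.48 with anti-HA. Across the 22 autosomes, which are not independent replicates, the densities of the HepG2 lists correlated with r of 0.97 (rho 0.89) and those of the Huh7 lists with r of 0.67 (rho 0.85), or 0.94 without the 2 farthest chromosomes, 19 and 22. Chromosome 19 set the Huh7 lists apart, at 2.55 times (2.33 to 2.79) the median autosome with anti-HOXA13 and 1.10 times (1.01 to 1.19) with anti-HA. The 4 correlations across lines lay at r of 0.24 or below. All 6 pairs of lists were computed.

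Strong anti-HOXA13 peaks gathered on chromosome 19 in Huh7 and on chromosome Y and near centromeres in HepG2. Chromosome 19, the most gene-dense human chromosome and home to many zinc finger gene clusters, held 54 of the 266 strong Huh7 anti-HOXA13 peaks, 11.6 times (8.69 to 15.1) the density of the median autosome. Without raised input it held 50 of 230 (21.7%, 16.6 to 27.6%), in 34 groups of peaks within 100 kb of each other. Chromosome Y held 157 of the 542 strong HepG2 anti-HOXA13 peaks (29.0%, 25.2 to 33.0%) and 23 of the 95 without raised input (24.2%, 16.01 to 34.1%), and chromosome X held 51 and 0. On chromosome 19, HepG2 anti-HOXA13 held 22 of its 95 strong peaks without raised input (23.2%, 15.1 to 32.9%). However, 21 of them lay in 2 stretches, 36763066 to 36798968 and 37770728 to 37793364. HepG2 anti-HA held 29 and 14 peaks in these stretches, with 1 strong peak in each. Huh7 anti-HOXA13 held 1 and 2 peaks there, 0 of them strong, and Huh7 anti-HA held 0 and 1. HepG2 anti-HA placed 57 of 5141 (1.11%, 0.841 to 1.43%) on chromosome 19, which makes up 1.99% of the covered length. Of the strong autosomal HepG2 anti-HOXA13 peaks, 231 of 334 (69.2%, 63.9 to 74.1%) lay within 1 Mb of the 18 autosomal peak-free stretches of at least 2.9 Mb, taken as the centromere gaps of GRCh37, against 2.48% (2.13 to 2.87%) in HepG2 anti-HA, 2.26% (0.832 to 4.84%) in Huh7 anti-HOXA13 and 16% (9.63 to 24.4%) in Huh7 anti-HA.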

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

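Tests of chromosome 20 among strong anti-HA peaks, of anti-HA overlap without raised input, of 5-fold peaks in HepG2, of anti-HA libraries from untagged cells and of chromosome 19 in Huh7 anti-HA were chosen after their results were seen; the other tests below were written down first.

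Peaks outside the chromosomes were set apart because the comparisons did not use them. The decoy sequence, which collects human sequence missing from the chromosomes, held 9857 peaks in HepG2 anti-HOXA13, 5272 in HepG2 anti-HA, 256 in Huh7 anti-HOXA13 and 1218 in Huh7 anti-HA. On GL000220.1, an unplaced contig that carries ribosomal DNA, the highest fold was 16 in HepG2 anti-HOXA13, 17.6 in HepG2 anti-HA, 1.84 in Huh7 anti-HOXA13 and 2.67 in Huh7 anti-HA.

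The density of weak HepG2 peaks on chromosomes 20, 16, 2, 6 and 14 was shared by both antibodies. More binding of the tagged protein there is argued against by its strong peaks, whose density on chromosome 20 was 1.5 times (1.31 to 1.71) the median autosome where that of weak peaks was 5.98 times. Without raised input the density of strong peaks there was 0.669 times (0.525 to 0.842) the median autosome. Raised input was set against the genome background of the list, so a chromosome with deeper input would lose more peaks. That lower value therefore does not add to the argument. Raised input lay under only 1309 of the 71999 HepG2 anti-HOXA13 peaks. Leaving these out could not bring the chromosome 20 ratio below 2, the limit set beforehand, so that test decides nothing. The ratio was 5.80 (5.67 to 5.94) without them, and 7127 of the 7144 chromosome 20 peaks had no raised input. A copy number above that of other chromosomes, which is known for several of these chromosomes in HepG2, may bring more weak calls past a fixed p; the weak peaks of the HepG2 lists then need not coincide. They coincided on chromosome 20 in 122 cases, 1.26 times the shift mean of 96.9 and just above the highest shift of 120, which neither meets chance nor reaches the 2 times set beforehand, so this explanation stays open.

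Anti-HA lists shared regions between lines, and few anti-HA peaks were shared with anti-HOXA13 in the same line. Raised input as the whole cause is argued against by 1094 overlaps of the anti-HA lists without it, 8.71 times the shift mean, the highest shift being 152. Chance calls that hide a common set were tested with the peaks of at least 5-fold. In Huh7, 1.46% (0.301 to 4.20%) of the anti-HOXA13 peaks were held by Huh7 anti-HA. Of the Huh7 anti-HA peaks, 63.6% (40.7 to 82.8%) were held by HepG2 anti-HA. The lists searched differed in strength, with 115 strong peaks in Huh7 anti-HA and 7537 in HepG2 anti-HA. A common set missed by the weaker list would give the same contrast, so the test decides nothing in Huh7. In HepG2 chance calls also stay open, as 43.8% (33.3 to 54.7%) of such anti-HOXA13 peaks were held by HepG2 anti-HA. Signal that the anti-HA antibody may give without the tagged protein cannot be told apart from binding of tagged HOXA13, since 0 of the 12 libraries paired the anti-HA antibody with untagged cells. Higher expression of the tagged protein, or an HOXA13 antibody that also meets other proteins, stays open and was not tested.

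Strong Huh7 anti-HOXA13 peaks gathered on chromosome 19. Extra copies of the chromosome are argued against by Huh7 anti-HA, where its density was 1.15 times (1.06 to 1.24) the median autosome against 3.00 times (2.77 to 3.25) in Huh7 anti-HOXA13. Raised input lay under only 36 of the 266 strong peaks. Leaving these out could not bring the chromosome 19 share down to its 1.99% of the covered length, so that test decides nothing. The share was 21.7% (16.6 to 27.6%) without them, and 50 of the 54 chromosome 19 peaks had no raised input. Binding that the tagged protein shares was tested by overlap with either anti-HA list. Of the 54 peaks, 3 overlapped, within the 0 to 4 given by shifts, with an upper limit of 15.4%. Huh7 anti-HA, the only anti-HA list of this line, held 115 strong peaks, 4 of them on chromosome 19. Absence from so weak a list cannot decide whether the binding is shared. HOXA13 binding that tagged cells lack and cross-reaction of the HOXA13 antibody both remain candidate explanations, untested here.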

How the results depend on the processing

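The limits on q of 0.05 and on raised input were chosen after the data were seen; the other alternatives were fixed before. Over 42 alternatives, 12 values stayed within their counting interval or within 1.5 times the count, 30 moved, and no excess over chance reversed. The 12 include the peak counts without merging, which equal the main counts because no list held peaks that overlapped each other. They also include the peak counts on all sequences. Ratios of observed to chance overlap are given in the order HepG2 anti-HA in anti-HOXA13, Huh7 anti-HA in anti-HOXA13, anti-HOXA13 between lines and anti-HA between lines, from main values of 3.72, 4.45, 2.77 and 16.9. With summits inside the other peak they were 6.75, 5.69, 3.72 and 22.9, and with 50% of the peak covered 7.67, 5.85, 3.62 and 23.2. With shifts by 10 to 50 kb as chance they fell to 2.20, 2.99 and 12.6, with anti-HOXA13 between lines the same within its interval. Equal list lengths gave 18.3, 6.55 and 43.5 and q of 0.05 gave 20.6, 24.8 and 94.5, each for the pairs other than the Huh7 pair, which stayed the same. Strong peaks gave 128, 33.3 and 352 for the same pairs; the Huh7 pair then had 0 overlaps where 0.03 were expected by chance, so no ratio was formed. These ratios are over placements. Over shifts, equal list lengths, q of 0.05 and strong peaks gave 3.47, 3.50 and 2.98 for the HepG2 pair. For anti-HOXA13 between lines they gave 4.65, 11.6 and 66.7, the last from 2 overlaps. For anti-HA between lines they gave 18.6, 25.3 and 18.1. Without raised input the ratios over placements were 2.79, 2.12 and 9.90, with the Huh7 pair the same. Shorter lists lower the chance count by construction; the cause of the other shifts was not tested. Regions in all lists numbered 4, and 0 among strong peaks, 2 at equal list lengths and 0 without raised input. Strong peaks numbered 542, 7537, 266 and 115 in HepG2 anti-HOXA13, HepG2 anti-HA, Huh7 anti-HOXA13 and Huh7 anti-HA, while counts on all sequences stayed within 1.5 times those on the chromosomes. Other settings for promoters, HOX13 sites and gene lists, fixed before, were not run, since no GRCh37 sequence or annotation was used here. Counting limits weak peaks most: the median summit held 7 to 14 ChIP fragments. No paired analysis was possible because each condition had 1 library.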

Other observations

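All tests in this part were chosen after the data were seen. Regions held by both HepG2 lists and by neither Huh7 list were led by 3 regions on chromosomes 8, 1 and 12. Chromosome 8, 70602311 to 70602557, stood at 20.6-fold with anti-HOXA13 and 19.95-fold with anti-HA, chromosome 1, 91852750 to 91853132, at 21.7-fold and 10.1-fold, and chromosome 12, 20704323 to 20704531, at 22.9-fold and 6.55-fold. Their Huh7 counterparts were weaker, the highest at 4.79-fold and 4.99-fold. The GL000220.1 contig showed the same contrast, with 16-fold and 17.6-fold in the HepG2 lists and 1.84-fold and 2.67-fold in the Huh7 lists. Repeat annotation was not used here, so it was not tested whether these regions, or the leading HepG2 anti-HOXA13 regions on chromosomes 5 and 21, carry copies of ribosomal DNA.

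Part of the Huh7 chromosome 19 set recurred in HepG2 with the same antibody. Of the 54 strong Huh7 anti-HOXA13 peaks on chromosome 19, 12 overlapped a HepG2 anti-HOXA13 peak, where 100 shifts gave a mean of 0.66 and a maximum of 3. Among them, 58708182 to 58708737 stood at 9.29-fold in Huh7 and 3.42-fold in HepG2, and 44980643 to 44981768 at 9.23-fold and 3.36-fold. The largest groups of strong Huh7 peaks without raised input on this chromosome were 7 peaks at 11979002 to 12187547 and 4 peaks at 2834233 to 2933871.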
